A study of Mus musculus with 6 samples.

How the data were processed

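Per the protocol in the labels, RNA from testes of 8-week-old mice was extracted with TRIzol, treated with DNase, made into libraries with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument. The 6 libraries were grouped by the genotype in their labels, 3 WT and 3 Ccdc117ko. The submitters' processing notes name STAR, DESeq2 and the mm10 build with no version; the role and order of these tools, the counting step and its use of strand are not given in the sources used here.

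The authors deposited 1 table of 36652 genes with a log2 value per library, which this work read as log2(normalized count + 1) from the values themselves, since the file headers do not state the unit. With 1 subtracted after undoing the log2, the values of each library were whole multiples of 1 step: 100% of values under 500 reads were whole within 0.01. The steps give whole reads, 35791616, 43461692 and 39939156 for WT replicates 1 to 3 and 39368277, 38521519 and 38964966 for Ccdc117ko replicates 1 to 3. Median-of-ratios factors recomputed from those reads equal the deposited scaling within rounding. The deposited table also holds the authors' means per genotype on the log2 scale, their log2 fold change, and their p-value and FDR, whose test the file does not state. These were used only for the counts and the FDR of Lhcgr credited to the authors' deposited table.

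The test design had been fixed for a table of counts, with limma as the choice for normalized values. As the deposited values are log2 of normalized counts, limma-trend (limma 3.58.1 in R 4.3.3) was fitted to them as deposited, with genotype as the only term, for the 32783 genes with a mean of at least 0.5 normalized counts over the 6 libraries. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Fold changes are on the log2(normalized count + 1) scale, which understates those of genes with few reads. Floors of 3 counts cover only the counting error of the group with no read. The reads of the other group are taken as exact, so a fold against the floor is not a lower bound.

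A set of 28 gene lists for testis cell types, germ cell stages, steroid and sterol synthesis, iron-sulphur proteins, stress, RNA quality, neighbouring tissues and the neighbours of Ccdc117, and the rule for named genes, were chosen before the data were examined. Lists were tested with camera in limma, with a preset correlation of 0.01 and with an estimated one, and with fry. Each was adjusted over the 28 lists. With the preset correlation 7 lists were called, and none with an estimated one. The estimated form takes its degrees of freedom from the few libraries rather than from the genes, so it has little power here. The Sertoli list had an estimated correlation of -0.014, below the preset, yet its unadjusted camera p went from 7.99e-08 to 0.00418. A call lost with an estimated correlation thus does not by itself show correlated members. The other called lists had estimated correlations above the preset. These were 0.545 (mitochondrially encoded), 0.263 (ribosomal protein), 0.237 (sterol synthesis), 0.227 (round spermatid), 0.187 (elongating spermatid) and 0.037 (spermatogonial). For these lists the camera p with the preset correlation may be too small. The fry test of movement in 1 direction was under 0.05 for the androgen metabolism, Sertoli, spermatogonial, round spermatid, iron-sulphur assembly, unfolded protein and ribosomal protein lists. The rule names Ccdc117, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 normalized count and no overlap between genotypes (predicted genes left out), up to 4 called members of each list or, with none called, the 2 most abundant, and 8 Leydig cell genes; Fdx1, Nr5a1, Gm27177 and Gm15446 were named outside it, after their values were seen.

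Coordinates, transcript length and GC content came from GENCODE M21 on GRCm38 (mm10), which matched 36551 of the gene identifiers and 32704 of those tested. Shared sequence was measured as the percent of 50-base words of the longest transcript of a gene found in another gene. For the length and GC correction, the deviation of each library from the gene mean was fitted with natural splines (knots at the 25, 50 and 75 percentiles) of log2 length and GC and the fit removed.

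No pair of libraries was a duplicate: the chi-square per degree of freedom between replicates of a genotype was 4.68 to 7.50. The steps were tested on simulated reads for the 32783 genes of this comparison, with 200 genes changed per run over 5 runs. Limma recovered 17.6% of changes of 1.25-fold, 54.0% at 1.5-fold, 73.6% at 2-fold and 88.4% at 3-fold, with a mean of 1.6 false calls among 118.4. A simulated rise of 1.2-fold in the round spermatid list gave a camera adjusted p of 9.11e-33 and no call of another list. Simulated genes were drawn independently and, for that test, without a length trend, while the real list had an estimated correlation of 0.227. That run therefore does not test the preset correlation on real lists. The changed genes were drawn only from those above a minimum level, so recovery among genes with few reads was not measured.

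Alternatives were another pseudocount, other filters on low values, a fold threshold, the replicate number as a block, each library left out and an estimated correlation. Chosen after seeing the data were limma-voom on the recovered reads, robust empirical Bayes, a mean of at least 10 normalized counts (alone and with each library left out), upper-quartile scaling and the length and GC correction. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the annotation, and matplotlib 3.10.9 drew the plots.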

Results

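RNA sequencing was performed on whole testes of 8-week-old mice, with 3 libraries labelled WT and 3 labelled Ccdc117ko. Ccdc117 encodes a coiled-coil protein, and the title of the series ties its loss to raised androgen production and to sperm formation. The deposited table holds 36652 genes, and the whole reads recovered from it came to 35791616 to 43461692 per library. The labels do not say whether the replicates came from separate mice, so p-values measure the spread between these samples. The first principal component carried 37.8% of the variance and set the WT libraries (-13.4, -20.2 and -29.5) apart from the Ccdc117ko libraries (17.5, 30.1 and 15.5).

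Ccdc117 itself was present at the same gene-level total under both labels. The gene (ENSMUSG00000020482) lies on the minus strand of chromosome 11, from 5528887 to 5542187 in mm10. Its normalized counts were 3657, 3826 and 3931 in the WT libraries and 3478, 3772 and 3908 in those labelled Ccdc117ko. The means were 3805 ± 138 and 3719 ± 220 (SD, n = 3 each), a log2 fold change of -0.03 with a standard error of 0.05 and a limma adjusted p of 0.763. The labels do not describe the allele, and a total over the gene cannot show the loss of a small part of it, so the table does not check the genotype of any library. Every direction below is that of the libraries labelled Ccdc117ko against those labelled WT.

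Across the transcriptome, many small differences separated the genotypes. Of 32783 genes tested, 2228 changed at an adjusted p under 0.05 in limma, 1212 higher and 1016 lower in the libraries labelled Ccdc117ko, and 1846 of them were protein-coding. The median absolute log2 change of these genes was 0.34, a fold of 1.26, and 143 of them changed by at least 1 on the log2 scale, 61 higher and 82 lower. All 2228 had no overlap between the 3 values of each genotype, as did 27.0% of the tested genes, where chance gives 10%. The authors' deposited table lists 4233 genes with an FDR under 0.05, 2117 higher and 2116 lower, and 2151 of those are among the 2228. The limma count depended on single libraries: it was 1268 without WT replicate 1, 12 without WT replicate 2, 21 without WT replicate 3, and 22, 6 and 8 without Ccdc117ko replicates 1, 2 and 3, while 5817 to 7349 genes had an unadjusted p under 0.05 against 7436 with all libraries. Most single-gene calls given below are therefore lost without any 1 of the last 5 of these libraries. Among genes with a mean of at least 10 normalized counts, a filter chosen after the data were seen, limma called 3798, and 1714 to 4021 with each library left out in turn. With a correction for transcript length and GC content the split was 1205 higher and 590 lower.

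Genes of testosterone synthesis in Leydig cells moved in both directions. Star, which carries cholesterol into mitochondria at the rate-limiting step, rose from 1764 ± 414 to 4072 ± 78.7 normalized counts (SD, n = 3 each), a fold of 2.35. Hsd3b6 rose from 2193 ± 360 to 3953 ± 163, while Hsd3b1, which encodes another 3-beta-hydroxysteroid dehydrogenase isoform, fell from 3078 ± 204 to 1651 ± 40.8. Cyp17a1, whose product makes androgens from progestins, rose from 9350 ± 802 to 12929 ± 846. The log2 fold changes were 1.23 for Star (SE 0.14, limma adjusted p = 0.0108), 0.86 for Hsd3b6 (SE 0.11, adjusted p = 0.0124), -0.90 for Hsd3b1 (SE 0.06, adjusted p = 0.000985) and 0.47 for Cyp17a1 (SE 0.07, adjusted p = 0.0169). Fdx1, the electron donor of the mitochondrial P450 enzymes, rose by 0.32 (adjusted p = 0.018), and Nr5a1, a transcription factor of steroid-producing cells, fell by 0.24 (adjusted p = 0.0357; 0.0588 after a correction for length and GC).

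Other steps of the pathway did not pass. Cyp11a1 had a log2 fold change of 0.21 (limma adjusted p = 0.26), Hsd17b3, which makes testosterone from androstenedione, -0.21 (0.209), and Lhcgr, the receptor of luteinizing hormone, -0.41 (0.126), although the authors' deposited table gives Lhcgr an FDR of 0.0124. Of the 17 steroidogenesis genes, 4 were higher, 2 lower and 11 not called, and adjusted over the list alone 5 were higher and 3 lower. With a median log2 change of 0.11, the list did not stand apart from other genes in camera (adjusted p = 0.189). Camera tests for a shift in 1 direction, so moves both ways can cancel in it. For scale, 6.80% of all tested genes were called. The fry test for changes in either direction, which makes no comparison with other genes, gave an adjusted p of 0.000183. That fry test was under 0.05 for most of the 28 lists. Among 13 Leydig cell markers outside the pathway the median was -0.04 (camera adjusted p = 0.403), with none higher and Vcam1, an adhesion molecule, lower at -0.57 (adjusted p = 0.0124). Adjusted over the list alone, 1 marker was again lower and none higher, and Insl3 had 0.24 (limma adjusted p = 0.113).

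Star lost its limma call without WT replicate 2 (adjusted p = 0.0669) or Ccdc117ko replicate 1 (0.0603), 2 (0.11) or 3 (0.0845). Hsd3b6 lost it without WT replicate 2 (adjusted p = 0.0618) or 3 (0.0917) or Ccdc117ko replicate 1 (0.0645), 2 (0.11) or 3 (0.0845), and Cyp17a1 without the same libraries (0.0691, 0.0933, 0.08, 0.118 and 0.0845). Hsd3b1 lost it without WT replicate 2 (adjusted p = 0.0524) or Ccdc117ko replicate 2 (0.0975) or 3 (0.0748). Among genes with a mean of at least 10, Star, Hsd3b6, Hsd3b1 and Cyp17a1 stayed at or under an adjusted p of 0.00812 whichever library was left out.

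**Figure D1:**
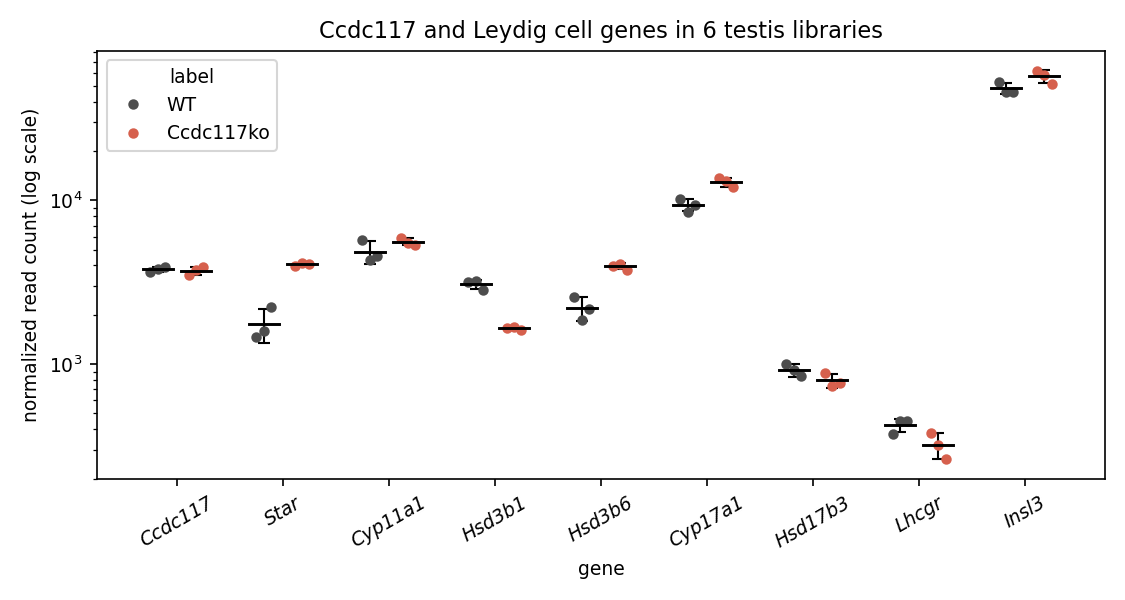
Normalized read counts on a log scale for Ccdc117 and 8 Leydig cell genes in each of the 6 libraries, with bars at the mean and error bars of 1 SD (n = 3). The 3 Ccdc117ko points of Star, Hsd3b6 and Cyp17a1 lie above all WT points, those of Hsd3b1 lie below, and those of Ccdc117 overlap.

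Genes of androgen metabolism were called both ways, with 12 of 18 below 0. The fry test of movement in 1 direction gave this list an adjusted p of 0.00264. Srd5a1, a steroid 5-alpha-reductase, rose by 0.46 on the log2 scale (limma adjusted p = 0.0458), while Shbg, which encodes the sex hormone-binding globulin, fell by 0.51 (adjusted p = 0.0172) and Hsd17b11 fell by 0.35 (adjusted p = 0.0397). Of 18 tested genes of androgen metabolism, 1 was higher, 2 lower and 15 not called, and adjusted over the list alone 1 was higher and 4 lower (median -0.05, camera adjusted p = 0.338). Cldn11, a tight junction claudin, fell by 0.20 and Tubb3 fell by 0.31 among 9 Sertoli genes that the androgen receptor is known to raise, with 0 higher, 2 lower and 7 not called, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.127). After the length and GC correction the median of these 9 genes was -0.14 and camera called them lower (adjusted p = 0.0191, and adjusted p = 0.208 with an estimated correlation).

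Genes of sterol synthesis under SREBP2 leaned higher. Cyp51 rose from 3620 ± 162 to 4482 ± 299 normalized counts (SD, n = 3 each), Sc5d rose by 0.29 on the log2 scale and Dhcr7, the last enzyme of one branch of cholesterol synthesis, rose by 0.47. Of 23 genes 3 were higher, none lower and 20 not called, and adjusted over the list alone 4 were higher. The median was 0.11 (limma camera adjusted p = 0.00117), and adjusted p = 0.56 with an estimated correlation.

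Among germ cell stages, most round spermatid genes on the list were higher. Acrv1, which encodes an acrosomal protein, rose from 6984 ± 609 to 9409 ± 498 normalized counts (SD, n = 3 each), Spaca1, needed for the acrosome, from 6185 ± 504 to 8258 ± 139, and Catsper4, a subunit of the sperm calcium channel, from 4160 ± 348 to 5682 ± 211. Txndc8 rose by 0.32 on the log2 scale (limma adjusted p = 0.0124). Of 20 round spermatid genes 13 were higher, none lower and 7 not called, and adjusted over the list alone 16 were higher and 1 lower. Their median was 0.27 (limma camera adjusted p = 1.13e-10), and adjusted p = 0.363 with an estimated correlation.

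Among spermatogonial genes, those called were lower. Kit, the stem cell factor receptor of differentiating spermatogonia, fell from 854 ± 64.9 to 595 ± 38.6 normalized counts (SD, n = 3 each), and Dazl, a germ cell RNA-binding protein gene, from 4982 ± 340 to 3880 ± 182. Etv5, a self-renewal factor, fell by 0.44 on the log2 scale (limma adjusted p = 0.0124). None of the 22 was called higher, 3 were lower and 19 not called, 8 had a log2 change above 0, and adjusted over the list alone 5 were lower. The median was -0.15 (limma camera adjusted p = 0.0124), and adjusted p = 0.363 with an estimated correlation; without WT replicate 1 the camera adjusted p was 0.0826.

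Genes of the stages between and after these went both ways. Of 29 tested genes of meiotic prophase 2 were higher and 2 lower, Rec8 at 0.28 and Syce3 at 0.24 against Dmc1 at -0.26 and Mei1 at -0.34, and 25 were not called (median -0.04, limma camera adjusted p = 0.471; adjusted over the list alone, 3 higher and 4 lower). Of 18 pachytene genes Spag6 and Cdc25c were higher at 0.37 and 0.31, Mybl1, a meiotic transcription factor, was lower at -0.37, and 15 were not called (median -0.05, camera adjusted p = 0.628; adjusted over the list alone, 2 higher and 2 lower). Elongating spermatid genes had 4 higher, 1 lower and 19 not called of 24, and 8 higher and 2 lower adjusted over the list alone. Their median was 0.06 (limma camera adjusted p = 0.0265, and adjusted p = 0.56 with an estimated correlation), and Hils1, a spermatid linker histone, rose from 18459 ± 518 to 22390 ± 544 normalized counts (SD, n = 3 each). After the length and GC correction the median was 0.02 and the camera adjusted p 0.725. The camera call of this list was lost without WT replicate 3 (adjusted p = 0.064) or Ccdc117ko replicate 2 (0.113).

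Among Sertoli cell genes, those called were lower. Kitl, the ligand of Kit, fell from 602 ± 5.77 to 458 ± 20.5 normalized counts (SD, n = 3 each), Inhbb, an inhibin and activin subunit, from 1211 ± 34.1 to 934 ± 81.9, Dhh, a hedgehog ligand, from 933 ± 24.5 to 763 ± 10.4, and the transcription factor Gata4 from 1331 ± 31.6 to 1124 ± 19.5. Of 21 genes none was higher, 8 were lower and 13 not called, and adjusted over the list alone 11 were lower. The median was -0.17 (limma camera adjusted p = 7.46e-07), and adjusted p = 0.117 with an estimated correlation. After the length and GC correction 5 were lower, and Dhh, Inhbb and Gata4 were no longer called (limma adjusted p = 0.105, 0.0696 and 0.0845).

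The other somatic lists had medians below 0 without a call. Peritubular myoid genes had 1 higher, Actg2 at 0.20, 1 lower, Myh11 at -0.26, and 10 not called of 12 (median -0.11, limma camera adjusted p = 0.127; adjusted over the list alone, 1 higher and 2 lower). Of 16 macrophage genes Aif1 was higher at 0.22, Fcgr3 and Mrc1 were lower at -0.35 and -0.28, and 13 were not called (median -0.11, camera adjusted p = 0.392; adjusted over the list alone, 1 higher and 2 lower). Aif1 had a WT mean of 10948.5 normalized counts, against 981 for Mrc1 and 145 for Cd68. Actg2 had 9588, against 2390 for Acta2 of the same list. Whole-testis reads do not show which cells they came from, so both rises may lie outside macrophages and myoid cells. No endothelial gene of 13 was called (median -0.16, camera adjusted p = 0.127), with Sox17 at -0.32 and Vwf at -0.02. Of 7 red cell genes none was called (median -0.28, camera adjusted p = 0.262), with Alas2 at -0.17 and Hbb-bs at -0.28, the last sharing reads with a near-identical globin. Neighbouring tissues gave 0 calls, over 11 epididymal genes (median 0.39, camera adjusted p = 0.845; Rnase10 at -0.37, Spink8 at 0.39) and 9 fat cell genes (median -0.15, camera adjusted p = 0.392; Lipe at -0.15, Adipoq at 0.43). Adjusted over the list alone, these 4 lists also had 0 higher and 0 lower. Without Ccdc117ko replicate 1, limma camera called the peritubular (adjusted p = 0.0283), endothelial (0.0424) and red cell (0.0485) lists.

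**Figure D2:**
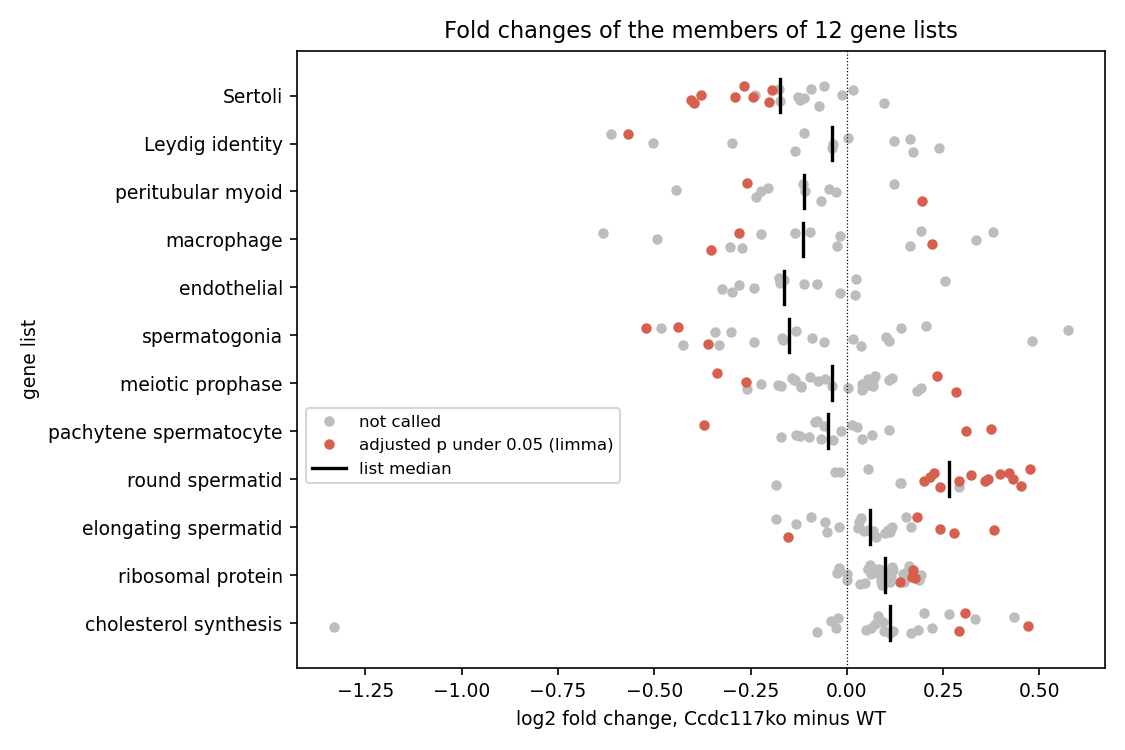
Log2 fold changes (Ccdc117ko minus WT) of the members of 12 gene lists, 1 point per gene, coloured where the limma adjusted p was under 0.05, with a bar at the list median. The round spermatid median lies at 0.27 and the Sertoli and spermatogonial medians at -0.17 and -0.15.

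Fold changes followed transcript length. Across 14256 protein-coding genes with a mean of at least 50 normalized counts, Spearman's rho between log2 fold change and length was -0.389, where genes are not independent replicates. The median log2 change ran from 0.10 in the shortest of 5 bins of these genes to -0.14 in the longest. The slope per doubling of length was 0.049, 0.024 and 0.060 in WT replicates 1 to 3 and -0.042, -0.062 and -0.028 in Ccdc117ko replicates 1 to 3. The trend thus ran with genotype, and removing it also removes any genotype change tied to length. After a smooth trend with length and GC was removed from each library, rho was -0.0227. The round spermatid (median 0.26), Sertoli (-0.17) and spermatogonial (-0.15) lists kept their limma camera calls with the preset correlation (adjusted p = 2.98e-10, 3.77e-08 and 0.0052), and none was called with an estimated correlation (0.191, 0.0835 and 0.191). Of 83 named genes past the threshold, 28 lost their limma call with the correction: Aco1, Actg2, Aif1, Ascc2, Bola1, Creld2, Cyp2c39, Ddx11, Dhh, Ern1, Gata4, Igkv8-28, Inhbb, Mdc1, Mei1, Mrc1, Myh11, Pcna, Prm3, Rpl30, Rpl7, Rps14, Sec14l2, Stfa2l1, Syce3, Tekt4, Tyw1 and mt-Nd3 (adjusted p between 0.0533 and 0.582). A lost call is not a lost fold: the log2 change of Cyp2c39 went from 2.14 to 2.06, Stfa2l1 from 2.20 to 2.04, Igkv8-28 from 1.84 to 1.72, Sec14l2 from -0.39 to -0.35 and Aco1 from -0.39 to -0.30, against 0.14 to 0.04 for Rps14.

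**Figure D3:**
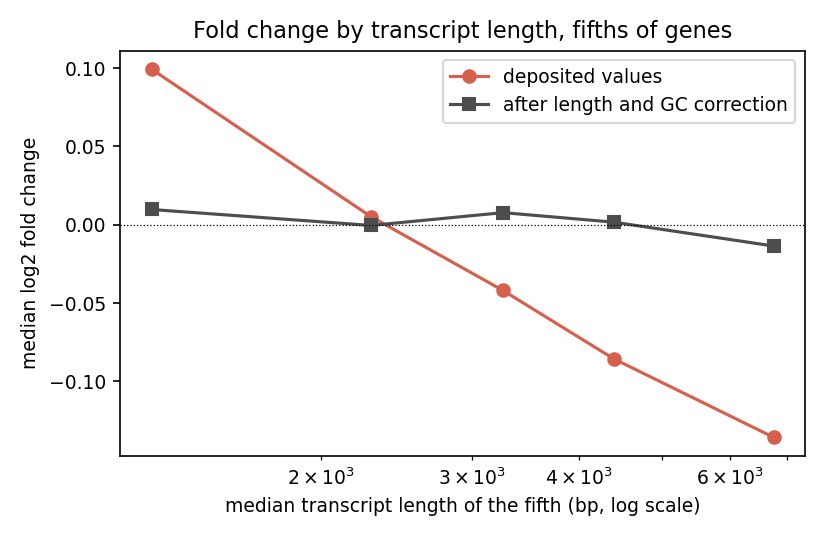
Median log2 fold change against median transcript length (bp, log scale) for 5 bins of 14256 protein-coding genes, before and after the length and GC correction. The median falls from 0.10 to -0.14 with length before the correction.

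Among ribosomal protein genes, the few called were higher by a small amount. Rpl7 rose from 7106 ± 58.3 to 8037 ± 229 normalized counts (SD, n = 3 each), and Rpl30, Rpl18 and Rps14 rose by 0.17, 0.17 and 0.14 on the log2 scale. Of 36 genes 4 were higher, none lower and 32 not called, and adjusted over the list alone 12 were higher (median 0.10, limma camera adjusted p = 3.42e-08, and adjusted p = 0.446 with an estimated correlation). After the length and GC correction the median was 0.01 and the camera adjusted p 0.287. Mitochondrially encoded transcripts, taken as a sign of RNA quality, had mt-Nd3 higher at 0.36, mt-Nd5 and mt-Rnr2 lower at -0.25 and -0.28, and 12 not called of 15, with 1 higher and 3 lower adjusted over the list alone. Their median was -0.07 (limma camera adjusted p = 0.0385, and adjusted p = 0.56 with an estimated correlation), and the camera call was lost without WT replicate 1 (adjusted p = 0.222) or 3 (0.064) and without Ccdc117ko replicate 1 (0.0605) or 3 (0.335). It was also lost with at least 1 CPM in 3 libraries (adjusted p = 0.0962), the replicate block (0.0561), a mean of at least 10 (0.0559) and upper-quartile scaling (0.0886). After the length and GC correction their median was -0.23, with 8 lower and 0 higher (camera adjusted p = 4.70e-10, and adjusted p = 0.333 with an estimated correlation).

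Few iron-sulphur cluster genes were called. Among 28 tested assembly factors Nubpl, a factor for complex I, rose by 0.41 and Bola1 by 0.24, none was lower and 26 were not called (median 0.08, limma camera adjusted p = 0.0609; adjusted over the list alone, 7 higher and 1 lower). Camera called the assembly list higher after the length and GC correction (adjusted p = 0.0133, and adjusted p = 0.191 with an estimated correlation), with upper-quartile scaling (0.0308), with no filter on low values (0.0478) and without WT replicate 2 (0.0385), and its fry adjusted p was 0.0186. Of 26 proteins that carry such a cluster, the helicase gene Ddx11 fell by 0.27, Aco1, the cytosolic aconitase and iron regulator, fell by 0.39 and Tyw1 fell by 0.30, none was higher and 23 were not called (median -0.03, camera adjusted p = 0.338; adjusted over the list alone, 1 higher and 4 lower). Bola1, Ddx11, Aco1 and Tyw1 lost their limma calls after that correction (adjusted p = 0.247, 0.106, 0.0644 and 0.19), which called 2 of the 26 proteins higher and 0 lower.

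Camera called none of the damage and stress lists on the deposited values. None of 23 p53 targets was called in limma on the deposited values, with Mdm2 at 0.17 (adjusted p = 0.0624) and Sesn2 at -0.23 (0.0501; list median 0.04, while camera pointed down with an adjusted p of 0.861). Mdm2 was called higher after the length and GC correction (0.20, limma adjusted p = 0.0265), and both were called among genes with a mean of at least 10 (0.0263 and 0.0201). Replication and repair genes had Chek1 and Pcna higher at 0.38 and 0.18, Mdc1 lower at -0.25 and 24 not called of 27 (median -0.09, limma camera adjusted p = 0.0902; adjusted over the list alone, 2 higher and 6 lower), and without Ccdc117ko replicate 3 the camera adjusted p was 0.0308. Of 20 genes of the unfolded protein response Creld2 was higher at 0.21, Pdia4 and Ern1 were lower at -0.20 and -0.42, and 17 were not called (median -0.11, camera adjusted p = 0.0609; adjusted over the list alone, 1 higher and 7 lower). After the length and GC correction camera called that list lower (adjusted p = 0.015, and adjusted p = 0.191 with an estimated correlation), and its fry adjusted p on the deposited values was 0.00353. No interferon-stimulated gene of 21 changed (median -0.06, camera adjusted p = 0.789), with Stat2 at -0.03, nor did any NRF2 antioxidant gene of 20 on the deposited values, with Gpx4 at 0.12 and Gstm1 at 0.07 (median -0.02, camera pointing up, adjusted p = 0.76), while the length and GC correction called 1 higher and 1 lower. Adjusted over the list alone, the p53, interferon and antioxidant lists had 0 higher and 0 lower. Of 20 immediate early genes, which rise during dissection, Egr3 was higher at 0.31, 19 were not called, and 3 were higher and 1 lower adjusted over the list alone (median 0.07, limma camera adjusted p = 0.403).

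With predicted genes left out, the largest fold changes sat in genes with few reads. Sox14, a transcription factor gene, fell from 41.6 ± 6.74 to 4.37 ± 1.57 normalized counts (SD, n = 3 each; limma log2 fold change -3.01, adjusted p = 0.00948), and Fetub, which encodes the secreted protein fetuin-B, rose from 21.7 ± 4.40 to 95.6 ± 38.8 (2.01, adjusted p = 0.0201). Srrm3, a splicing factor gene, rose by 1.33 on the log2 scale. Gabrr3, a GABA receptor subunit gene, had no read in the libraries labelled Ccdc117ko and was 14.8-fold lower there against a floor of 3 counts over the group. On the same floor Slc7a10 was 7.27-fold lower, Gpr82 6.38-fold, Pcdhb11 5.95-fold, Vmn2r-ps24 5.70-fold, Krt86 5.43-fold and Nt5c1a 5.17-fold. In the other direction, genes with no read in the WT libraries were, on that floor, 7.15-fold higher for Qrfp, 6.81-fold for Ccl19-ps1 and 4.43-fold for Rtl3. Olfr324 was 4.41-fold higher, Stfa2l1 4.06-fold, Cyp2c39 3.74-fold and Igkv8-28 2.72-fold. These folds rest on few reads, down to 8 over the libraries labelled Ccdc117ko for Igkv8-28. Tubb4a had 2 reads in the WT libraries together and 23 in the others, and Vmn1r88 had 60 and 3. Ccl19-ps1, Krt86 and Igkv8-28 share over 50% of their 50-base words with other transcripts, and Speer4cos, which fell from 38.1 ± 2.21 to 4.04 ± 2.02, lies in a cluster of near-identical copies, so the assignment of their reads is uncertain. Some predicted genes had larger rises, among them Gm27177, from 2.73 ± 1.73 to 82.0 ± 1.79 (4.60 on the log2 scale), and Gm15446, from 18.0 ± 1.69 to 185.5 ± 16.4 (3.30), with 97.2% and 61.2% of their sequence words shared.

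Of 26 genes beside Ccdc117 on chromosome 11, none was higher, 4 were lower and 22 not called. Mtmr3 fell by 0.33, Castor1 by 0.45, Ascc2 by 0.20 and Sec14l2 by 0.39 on the log2 scale, with limma adjusted p between 0.0198 and 0.0425. Adjusted over the list alone 1 was higher and 7 lower (median -0.04, limma camera adjusted p = 0.159). After the length and GC correction 1 was higher and 2 lower (median -0.003). Ascc2 and Sec14l2 were then no longer called (limma adjusted p = 0.223 and 0.0578).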

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

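Limma-voom, robust empirical Bayes, the mean of at least 10, upper-quartile scaling and the length and GC correction were chosen after the data were seen. The planned TMM, RLE and upper-quartile factors in edgeR, the DESeq2 test and the robust quasi-likelihood fit were planned only for a deposited table of counts and were not run; limma-voom on the recovered reads was the count-based test that was. Against 2228 genes changed (1212 higher, 1016 lower), limma called 4127 (2048 and 2079) with at least 1 CPM in 3 libraries, 3798 (1911 and 1887) with a mean of at least 10 normalized counts, and 143 (61 and 82) with a log2 change of at least 1. The length and GC correction left 1795, with 1205 higher and 590 lower. The other settings gave 2150 to 3121. Of the 2228, 2179 were called by limma-voom on recovered reads, 1266 after the length and GC correction and 2145 with a mean of at least 10. Leaving out 1 library gave 6 to 1268 genes changed, 2 to 789 higher and 4 to 479 lower. The prior degrees of freedom in limma were 3.86 with all libraries and 1.95 to 2.63 with 1 left out, against 8.82 and 8.01 to 9.81 with a mean of at least 10, where leaving out 1 library gave 1714 to 4021. All 83 named genes that passed kept their direction in each of the 6 fits with a library left out, but lost their call in 455 of those single-gene tests. Of the named genes, 57 lost their call with the replicate block and 28 with the length and GC correction. With the replicate number as a block, limma called 703 (364 higher, 339 lower). Same-numbered libraries deviated with correlations of -0.08, -0.05 and 0.04, against -0.10 to 0.13 for libraries of different numbers, so no pairing by number was seen. With 3 libraries per genotype this cannot exclude a pairing, and the labels do not state one. With an estimated correlation, camera called 0 of the 7 lists; leaving out 1 library gave 5 to 9, and the other settings 6 to 8. The length and GC correction called 8, of which 5 were among the 7: the elongating spermatid and ribosomal lists were lost, and the iron-sulphur assembly, unfolded protein and androgen-response Sertoli lists gained. The Leydig steroidogenesis list stayed uncalled in every setting (adjusted p 0.0826 to 0.56). Ccdc117 stayed uncalled in every setting, but its sign turned with the length and GC correction (0.0194), and its log2 fold change ran from -0.0703 to 0.0138 with 1 library left out. That correction also turned the uncalled Gstm1 (-0.0116), Stat2 (0.0749) and Vwf (0.145) and the uncalled epididymal (adjusted p 0.914), pachytene (0.914), iron-sulphur client (0.67) and p53 (0.902) lists; the cause was not tested. With 1 library left out, the sign of Stat2 (-0.123 to 0.0964) and Vwf (-0.0637 to 0.0397) turned, as did the epididymal (adjusted p 0.453 to 0.926), immediate early (0.121 to 0.878), interferon (0.592 to 0.98) and p53 (0.592 to 0.923) lists, all uncalled.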

Other observations

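Tests on the number of loci, on copy families, on somatic lists, on Leydig cell number and on Hsd3b sequence were chosen only after the result was seen, as were the genes of the next paragraph.

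Among called genes with a mean of at least 100 normalized counts and under 10% shared 50-base words, Osbpl5, a lipid transfer protein gene, had the largest fall, from 906 ± 54.4 to 276 ± 31.1 normalized counts (SD, n = 3 each), a log2 fold change of -1.72 with a limma adjusted p of 0.000546. This ranking left out predicted genes and opposite-strand transcripts, and Abca1, Lipg, Aqp2, Ide and Ass1 were picked outside it. Abca1, the exporter of cellular cholesterol, fell from 1042 ± 61.7 to 652 ± 72.3, and Lipg, the endothelial lipase, from 757 ± 31.7 to 470 ± 22.1. Next in the ranking, Rab4a, a small GTPase of endosome recycling, fell by 1.08 on the log2 scale, Clic6 by 1.04 and Il17rb by 1.01. Mbp fell by 0.96, Sardh, the sarcosine dehydrogenase, by 0.86, Olig1 by 0.85 and B4galt6 by 0.83. Star had the largest rise, followed by Inpp5j at 0.93, Cstdc2 at 0.91 and Itih2 at 0.89. Kcnab1 and Heatr9 each rose by 0.69. Tac1, the precursor of substance P, rose from 161 ± 4.31 to 269 ± 16.1, and Gsta3, a glutathione transferase that also isomerises steroids, from 961 ± 50.7 to 1550 ± 59.2. The water channel Aqp2 rose by 0.63 and Ide, the insulin-degrading enzyme, by 0.62, from 9351 ± 257 to 14528 ± 2329. Ass1, the argininosuccinate synthase, rose by 0.95, with 60.8% of its sequence words shared with other transcripts.

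The change in the steroid genes was not a uniform rise of Leydig cell transcripts. The median log2 change of 13 Leydig identity markers was -0.0390, against 0.616 for 0.5 of the rise of Star on the log2 scale. Its standard error of 0.101 took the markers as independent, while their estimated correlation was 0.424. That error therefore does not measure the spread between libraries. The largest log2 change among the 13 markers was 0.24, also below 0.616, which argues against more Leydig cells as the whole cause. Hsd3b1 lost 46.3% of its reads while 5.70% of its 50-base words occur in Hsd3b6, which argues against shared words as the whole cause of its fall, and 5 of 5 genes (Star, Hsd3b6, Cyp17a1, Fdx1 and Hsd3b1) stayed called in limma after the length and GC correction, while Nr5a1 did not (adjusted p = 0.0588). Hsd3b1 and Hsd3b6 together went from 5271 ± 424 to 5604 ± 204 normalized counts (SD, n = 3 each), a log2 change of 0.09, as an exchange of reads between them would also give. An effect of the genotype within Leydig cells and a strain difference at these genes were not tested and stay open.

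The round spermatid and ribosomal protein lists were called higher and the Sertoli and spermatogonial lists lower. A length and GC trend between libraries could account for the ribosomal list, whose limma camera adjusted p was 0.287 after the correction. As the length trend ran with genotype, the correction cannot tell a technical trend from a genotype change tied to length. The corrected adjusted p of the round spermatid (2.98e-10), Sertoli (3.77e-08) and spermatogonial (0.00520) lists argues against that trend as their whole cause. The same correction moved the median of the mitochondrially encoded list, taken as a sign of RNA quality, from -0.07 to -0.23 with 8 lower (limma camera adjusted p = 4.70e-10, and adjusted p = 0.333 with an estimated correlation), so a difference in RNA quality was not tested and stays open. A lower share of all somatic cells is consistent with the corrected Sertoli, peritubular, macrophage, endothelial and Leydig identity medians of -0.17, -0.10, -0.14, -0.07 and -0.08 (SE 0.0279, 0.0495, 0.0827, 0.0610 and 0.0994; permutation p of a difference 0.583). These SEs and that permutation p took genes as independent replicates and do not measure the spread between libraries. The Leydig identity median lies within its SE of 0, with 0 higher and 3 lower after the correction against 0 and 1 before. The steroidogenesis list, left out of that test, had a corrected median of 0.06 with 5 higher and 1 lower. That permutation p does not show that the lists moved alike, so a change within Sertoli cells stays open. Over all settings the adjusted p ran from 1.05e-11 to 0.363 for the round spermatid list, 3.77e-08 to 0.117 for the Sertoli list, 0.00520 to 0.363 for the spermatogonial list and 1.69e-09 to 0.446 for the ribosomal list, each highest with an estimated correlation, where none was called.

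Large changes were grouped. Of 234 called genes with a log2 change of at least 0.7, 34 lay in 5 windows of 2 Mb with at least 4 such genes, all in 1 direction, against at most 2 such windows in 1000 shuffles: Speer4 copies on chromosome 5 and Dynlt1b, Dynlt1c and Tmem181 pseudogenes on chromosome 17 lower, Fam205a and Ccl27b copies on chromosome 4 and copies on chromosomes 14 and Y higher. Reads were summed over every gene with at least 10% of its 50-base words in a called copy, and genes sharing less were left out. On chromosomes 17, 4 and 5 these sums changed by -0.50, 0.56 and -0.54, beyond the range of either genotype and the median change of the chromosome. That argues against reads shared among such copies as the whole cause there. On chromosome 14 the sum of 2.09 covers called copies only, and on Y the sum of 0.23 is no larger than the median of 0.24 of Y genes with a mean of at least 10, so shared reads stay open at both. The shuffles placed calls as independent genes, while the called copies at these loci shared a median of 77.3% to 100% of their 50-base words. Any cause that moves such copies together would exceed the shuffles, so the 5 windows do not by themselves point to a cause. A genotype-linked difference in copy number or strain DNA stays open, and cannot be separated from the knockout in this design. Within 5 Mb of Ccdc117, 11 of 138 genes were called (7.97%) against 6.79% elsewhere (one-sided Fisher's exact p = 0.337, odds ratio 95% interval 0.578 to 2.20), so DNA of another strain around Ccdc117 cannot be told apart from none.

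The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Of these, 1 split, the real one, gave as many as 2228 genes, and the highest of the others gave 2.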
